A study of Medicago truncatula with 9 samples.

How the data were processed

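RNA from mature seeds of Medicago truncatula was sequenced for the wild type R108 and for 2 lines with Tnt1 retrotransposon insertions, hsfa9-1 (NF10440) and hsfa9-2 (NF13157), which are in the R108 background per the labels. Each of the 3 genotypes had 3 libraries, and each library came from 50 seeds harvested from different plants, per the labels. Plants were grown in a culture room at 20 °C and 19 °C with 16 h of light, pods were dried at 43% relative humidity, and the seeds were kept at 20 °C before RNA was extracted, per the labels' protocols. Sequencing was on the BGISEQ-500 platform with 50 bp reads and a stated average of 24 M reads per sample, per the labels' protocols.

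The authors deposited FPKM values (fragment numbers scaled by transcript length and by mapped fragments) with 2 decimals for 42631 transcript models. The submitters' processing notes name HISAT, HISAT2, Bowtie2 and RSEM with no versions and no roles, and the genome build, the annotation and any filters are not given in the sources used here. Gene descriptions and ontology terms were taken as the authors paired them with the identifiers. A gene table of another assembly was not used. No read counts were used here, so count-based tests were not run and the absolute depth of each library is unknown. Relative depth was estimated from the ratios of low FPKM values shared by the libraries, in 2501 transcript models, and lay between 0.990 and 1.01 of the mean, and the estimator's largest error on simulated libraries was 0.0387%.

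FPKM values were summed over the transcript models of each locus, which gave 36695 loci, of which 4262 had more than 1 model. Loci with at least 1 FPKM in at least 3 libraries were tested, which kept 17508. Values were analysed as log2(FPKM + 1), and a log2 change is a difference of group means on that scale, so that it understates ratios at low FPKM. All 9 libraries entered 1 linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend and robust moderation, and p-values were adjusted by the Benjamini-Hochberg method over the tested loci of each comparison, with a threshold of 0.05. The comparisons were hsfa9-1 with R108, hsfa9-2 with R108, the loci called in the same direction in both, and hsfa9-2 with hsfa9-1, which tests whether the change from R108 differs between the mutants. Errors are SD over 3 libraries. All adjusted p-values of loci and lists come from limma unless another test is named.

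The 27 gene lists were defined by words in the descriptions. They were heat stress transcription factors, small heat shock proteins, HSP60, HSP70, HSP90 and ClpB chaperones, DnaJ co-chaperones, LEA proteins and dehydrins, seed storage proteins, oil body proteins, raffinose family oligosaccharide synthesis, ABA metabolism, ABA perception and signalling, dormancy and maturation regulators, gibberellin metabolism and signalling, auxin response and transport, ethylene synthesis and response, cell wall loosening, photosynthesis (a green tissue marker), flavonoid synthesis (a seed coat marker), lignin synthesis (a seed coat and pod marker), nodule-specific genes (a marker of another organ), pathogenesis-related proteins, NB-LRR disease resistance genes, antioxidant and detoxification, cytosolic ribosomal proteins, cell cycle and histones, DNA repair, proteasome and ubiquitin ligases without F-box proteins, and retroelements. Each list was compared with the other tested loci by camera in limma with a preset correlation of 0.01, adjusted over the 27 lists and 3 comparisons. camera with an estimated correlation and fry, which asks whether a list's members move on balance in a single direction, were the alternatives. Members were also counted with p-values adjusted over the list alone. Ontology and KEGG terms with 10 to 500 tested loci were tested by one-sided Fisher's exact tests against the tested loci, adjusted over 1028 terms.

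Loci named in the text were taken by a fixed rule. For each mutant against R108 and each direction it takes the 8 largest changes, and for both mutants the 10 largest of the smaller changes. These loci had an adjusted p under 0.05, a mean of at least 1 FPKM and an informative description. For the changes of each single mutant, all its libraries also had to lie beyond all R108 libraries. Per list and mutant it takes the 2 tested members with the lowest p. For the contrast between mutants it takes the 5 largest changes per direction under the same conditions, with no overlap of the mutants. It also takes tested loci described as regulators of abscisic acid or seed maturation. Members named outside it are said to be chosen after their values were seen. The lists, the rule, the model, the thresholds and the alternatives not described as added were chosen before the data were examined. No transcript model's description names HSFA9, so the targeted gene was not identified and the labels of the mutants were not checked against it. Whether it is among the loci described only as heat stress transcription factors is not known.

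The model was tested on simulated data for 17508 loci with 100 loci changed by a log2 of 0.5 and 100 by a log2 of 1 in hsfa9-1. For hsfa9-1 against R108 it called 40 of 100 loci changed by 0.5 and 95 of 100 loci changed by 1, with 4 false calls. For hsfa9-2 against hsfa9-1 it called 45 and 98 of 100, with 6 false calls. Far more loci were called in the real comparisons with R108, so these rates do not carry over to them. A simulated shift of the 93 DnaJ members was called by camera, and 0 of the 26 other lists were. Loci were simulated independently of each other. The simulation therefore does not test the preset correlation where members of a list vary together, as with an estimated correlation of 0.172 for small heat shock proteins. Because both mutants share the R108 libraries, unchanged groups that share a simulated control were simulated 20 times. All libraries were simulated there, those of R108 included, with independent loci. This gives the agreement that a shared control produces by random noise alone.

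Alternatives were median centring of the log2 values, a pseudocount of 0.1, no low-expression filter, a filter at 3 FPKM, fits of only the groups compared, the replicate number as a block, leaving out each library in turn, an adjusted p threshold of 0.01, and a minimum absolute log2 change of 1. Added after seeing the data were the transcript models as features, rescaling to equal totals (the TPM scale), leaving out the 100 most abundant loci with rescaling and centring, quantile normalization, and the storage protein list without leguminosin peptides. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.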

Results

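Transcript abundance was measured by RNA sequencing in mature seeds of 3 genotypes of Medicago truncatula, the wild type R108 and the Tnt1 insertion mutants hsfa9-1 and hsfa9-2, with 3 libraries of 50 seeds each. HSFA9 belongs to the heat stress transcription factors, which bind promoters of chaperone genes, and the mutants carry insertions in this gene by their names. Between 922800.58 (R108 replicate 1) and 981284.54 (hsfa9-2 replicate 2) FPKM were listed per library. At least 1 FPKM was reached by 16589.7 ± 21.7 (SD, n = 3) loci in R108, 16432 ± 10.5 in hsfa9-1 and 16339.7 ± 111 in hsfa9-2. The 10 most abundant loci held 8.91% ± 0.233 of all FPKM in R108, 9.16% ± 0.519 in hsfa9-1 and 10.9% ± 1.28 in hsfa9-2. Relative depth differed little between libraries (0.990 to 1.01), the absolute depth is unknown, and the targeted gene was not identified among the loci. In all that follows, values are mean FPKM ± SD of 3 libraries, adjusted p-values are from limma, and a log2 change is a difference of mean log2(FPKM + 1).

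The libraries separated by R108 against both mutants. The first principal component of the tested loci held 81.5% of the variance and placed R108 between −76.0 and −74.8, hsfa9-1 between 34.7 and 37.7, and hsfa9-2 at 32.4, 42.5 and 41.9. The second held 4.83% and parted hsfa9-1 (14.1 to 16.6) from hsfa9-2 (−24.2 to −4.98). Pearson correlations across loci, which are not independent replicates, were 0.987 to 0.993 within a genotype, 0.986 to 0.989 between the mutants and 0.907 to 0.921 between a mutant and R108.

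**Figure D1:**
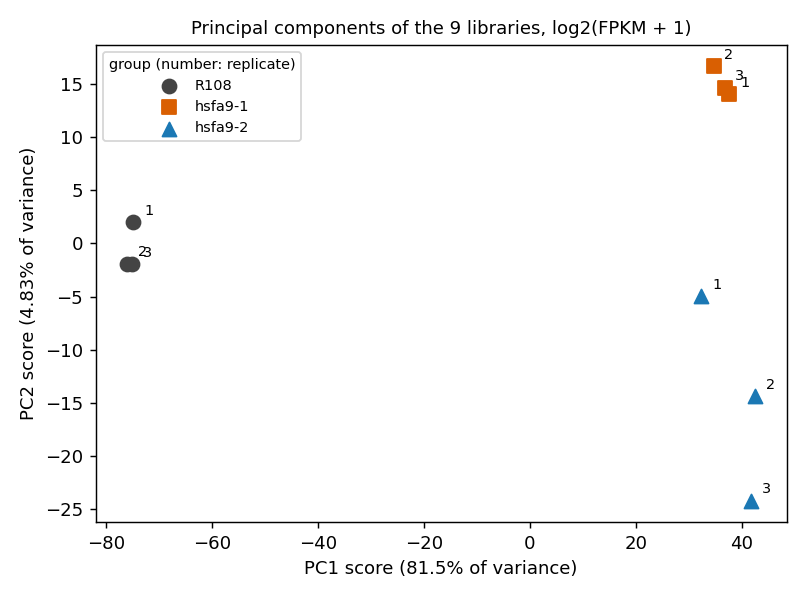
Principal components of log2(FPKM + 1) over the tested loci, with 1 point per library and the share of variance on each axis. R108 lies between −76.0 and −74.8 on the first component and the mutant libraries lie between 32.4 and 42.5.

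The comparison of hsfa9-1 with R108 asks which seed transcripts differ between an insertion line and the wild type. Among the described loci of the largest falls, transcripts of a few chaperones were nearly absent from hsfa9-1 seeds. The BAG domain locus Medtr8g028265, of a family of HSP70 co-chaperones, fell from 425 ± 14.2 FPKM in R108 to 1.89 ± 0.277 (log2 change −7.21, adjusted p = 2.09e-06). The HSP70 locus Medtr5g006180 fell from 241.5 ± 22.1 to 1.07 ± 0.225 (−6.88). The cytosolic class II small heat shock proteins Medtr8g022720 and Medtr3g092460 fell from 142 ± 21.5 to 0.217 ± 0.15 (−6.88) and from 92.0 ± 3.68 to 0.187 ± 0.122 (−6.30). In the other direction, the flavonol synthase locus Medtr4g093840 rose from 23.1 ± 3.63 to 1140.1 ± 82.4 (5.58, adjusted p = 8.08e-10). The xyloglucan endotransglucosylase/hydrolase Medtr4g128410, of a family that cuts and rejoins wall xyloglucan, rose from 0.297 ± 0.214 to 48.9 ± 4.44 (5.28).

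Among other described loci of the largest falls, a bidirectional sugar transporter (Medtr1g029380) fell from 307 ± 41.1 to 2.94 ± 0.218 FPKM (−6.28) and a light-harvesting complex I protein (Medtr5g098780) from 594 ± 60.5 to 7.44 ± 0.225 (−6.13). An equilibrative nucleoside transporter (Medtr2g011600) fell from 63.1 ± 5.22 to 0.25 ± 0.05 (−5.68), and the class II small heat shock protein Medtr3g104780 from 778 ± 109 to 15.9 ± 4.66 (−5.56). Rises of similar size were seen for an omega-hydroxypalmitate O-feruloyl transferase (Medtr8g096530; 2.46 ± 0.366 to 132 ± 12.1, 5.27), an enzyme type that acts on suberin precursors. A cysteine-rich stress tolerance protein (Medtr3g103210) rose from 0.08 ± 0.139 to 40.3 ± 2.21 (5.26). A GT8 glycosyltransferase (Medtr5g036580) rose from 2.79 ± 0.151 to 139 ± 18.8 (5.20), carotenoid cleavage dioxygenase 4a-6 (Medtr5g025270) from 0.683 ± 0.129 to 50.97 ± 4.27 (4.95). A cellulose synthase E1-like protein (Medtr3g060240) rose from 0.933 ± 0.159 to 52.1 ± 2.38 (4.78), and an EF hand calcium-binding protein (Medtr8g107110) from 3.45 ± 0.802 to 121 ± 21.3 (4.78).

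**Figure D2:**
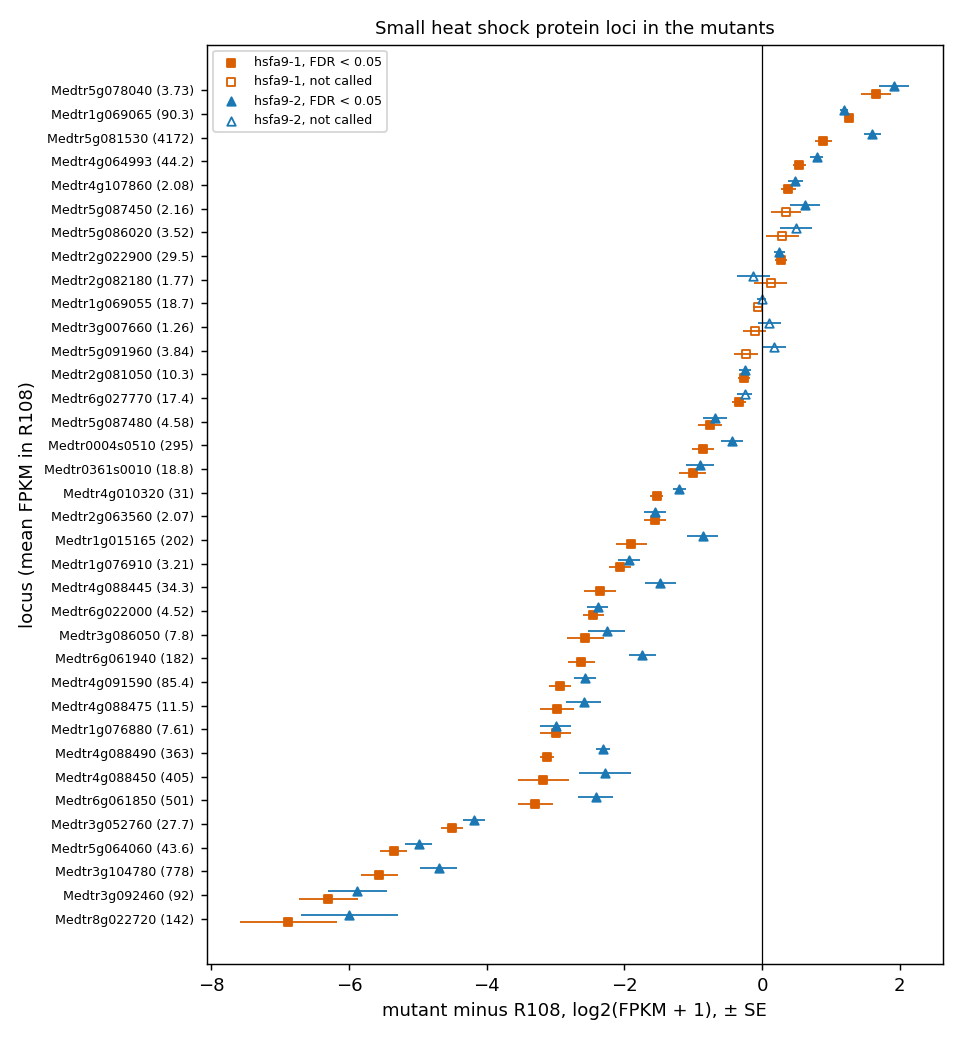
Change of each tested small heat shock protein locus against R108 as log2(FPKM + 1) on the horizontal axis, with bars of ± 1 standard error, squares for hsfa9-1, triangles for hsfa9-2, and open symbols for loci not called; the mean FPKM in R108 stands beside each locus. The lowest are class II locus Medtr8g022720 (−6.88 in hsfa9-1) and its neighbours in the plot, and the class I locus Medtr5g081530 lies above 0 in both mutants.

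Small heat shock proteins were the only chaperone list called by camera in hsfa9-1, with the preset correlation. Of the 36 tested small heat shock proteins, which hold unfolding proteins in solution, 24 fell, 6 rose and 6 were not called (24 and 6 adjusted over the list alone), with a median log2 change of −1.54. The list differed from other loci (camera adjusted p = 0.00145), with adjusted p = 0.742 with an estimated correlation. The class I locus Medtr4g088490 fell from 363 ± 48.2 to 40.7 ± 3.92 FPKM (−3.12) and the localized small heat shock protein Medtr3g052760 from 27.7 ± 3.34 to 0.267 ± 0.0924 (−4.50). Summed FPKM of the 4 loci described as class II small heat shock proteins was 1215 ± 151 in R108 and 71.6 ± 23.4 in hsfa9-1. That of the 11 class I loci was 5846 ± 301 and 7998 ± 780. The class I sum rested on Medtr5g081530, chosen after its values were seen, which rose from 4172 ± 12.8 to 7745 ± 718 (0.89), and without it the sum was 1674 ± 314 and 252 ± 65.8. Reads of near-identical copies may have been divided between these loci by the authors' quantification. Of 18 heat stress transcription factors, 8 fell, 4 rose and 6 were not called (8 and 4 adjusted over the list alone; camera adjusted p = 0.671), with 8 falls and 8 rises after median centring. Their median of 0.09 and mean of −0.44 differ in sign. Medtr5g089170 fell from 11.9 ± 1.54 to 0.197 ± 0.155 (−3.43) and Medtr4g088900 from 5.75 ± 0.58 to 0.09 ± 0.09 (−2.63). The 64 HSP60, HSP70, HSP90 and ClpB chaperones had 33 falls, 19 rises and 12 not called (34 and 19 adjusted over the list alone; camera adjusted p = 0.196). Against that balance the disaggregase ClpB (Medtr4g109450) rose from 319 ± 19.7 to 866.5 ± 30.3 (1.44) and a heat shock cognate 70 kDa protein (Medtr7g024580) from 129.5 ± 3.63 to 291 ± 3.33 (1.16). DnaJ co-chaperones fell at 31, rose at 22 and were not called at 40 of 93 loci (31 and 21 adjusted over the list alone; camera adjusted p = 0.727), with 30 falls and 30 rises without the 100 most abundant loci, rescaled and centred (chosen after the values were seen). Medtr4g085070 fell from 374 ± 13.3 to 29.3 ± 5.29 (−3.64). Medtr3g099170 rose from 17.0 ± 0.487 to 76.4 ± 3.35 (2.11).

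Reserve and desiccation lists went both ways in hsfa9-1, as did the 17508 tested loci as a whole, of which 4828 rose and 5584 fell. LEA proteins and dehydrins, many of which accumulate as seeds dry, rose at 28, fell at 22 and were not called at 13 of 63 loci (30 and 23 adjusted over the list alone; camera adjusted p = 0.537). The abundant LEA D-like locus Medtr1g072090 fell from 8195 ± 508 to 1744 ± 263 FPKM (−2.24). Medtr1g057420, which the word pattern caught by its description as a LEA hydroxyproline-rich glycoprotein, rose from 2.29 ± 0.56 to 38.4 ± 3.03 (3.59). Seed storage proteins, a list that by its word pattern also holds leguminosin peptides, rose at 11, fell at 10 and were not called at 10 of 31 loci (11 and 10 adjusted over the list alone; camera adjusted p = 0.840). Their median was 0.01 and their mean −0.06. A vicilin (Medtr7g079770) rose from 303 ± 21.5 to 872 ± 65.8 (1.52). Oil body proteins rose at 5, fell at 2 and were not called at 1 of 8 loci (5 and 2 adjusted over the list alone; camera adjusted p = 0.448), with 2 rises and 2 falls among the 5 left without the 100 most abundant loci. The oleosin Medtr6g005040 rose from 1521 ± 268 to 3729 ± 406 (1.30). The oleosin Medtr4g105200 fell from 158 ± 15.2 to 80.7 ± 12.8 (−0.97). Of 5 loci of raffinose family oligosaccharide synthesis, 3 rose, 1 fell and 1 was not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.306). Raffinose synthase Medtr3g075510 fell from 72.6 ± 3.04 to 5.06 ± 0.757 (−3.61) and Medtr3g110050 rose from 1.24 ± 0.351 to 11.1 ± 2.62 (2.43).

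Hormone lists also split, and none was called by camera. In ABA metabolism 2 loci rose, 1 fell and 1 was not called of 4 (2 and 1 adjusted over the list alone; camera adjusted p = 0.783). The 9-cis-epoxycarotenoid dioxygenase Medtr2g070460, which opens abscisic acid synthesis, rose from 1.64 ± 0.4 to 10.1 ± 1.33 FPKM (2.07), and zeaxanthin epoxidase Medtr5g017350 fell from 4.10 ± 0.585 to 1.22 ± 0.204 (−1.20). ABA perception and signalling had 9 rises, 9 falls and 4 not called among 22 loci (9 and 10 adjusted over the list alone; camera adjusted p = 0.727). The ninja-family protein AFP1 (Medtr3g025970) fell from 57.7 ± 7.13 to 2.69 ± 0.645 (−4.00). An abscisic acid receptor (Medtr5g083270) rose from 6.18 ± 0.0404 to 44.4 ± 5.51 (2.65). Of 4 dormancy and maturation regulators, 2 fell and 2 were not called (2 adjusted over the list alone; camera adjusted p = 0.448). The ABI3-interacting locus Medtr8g010160 fell from 13.4 ± 1.37 to 6.52 ± 0.834 (−0.94), phytochrome-interacting factor 3.1 (Medtr1g084980) fell from 69.9 ± 5.35 to 55.1 ± 1.65 (−0.34). The other ABI3-interacting locus, Medtr8g010170, had 260.0 ± 3.83 and 238 ± 11.1 (−0.13, adjusted p = 0.0667). Gibberellin loci fell at 11, rose at 7 and were not called at 8 of 26 (11 and 7 adjusted over the list alone; camera adjusted p = 0.804). Gibberellin 2-oxidase (Medtr4g096840), which inactivates gibberellins, rose from 2.27 ± 0.315 to 20.8 ± 0.765 (2.74). A gibberellin-regulated protein (Medtr1g018640) fell from 429.6 ± 65.0 to 50.1 ± 10.01 (−3.08). Auxin loci rose at 33, fell at 28 and were not called at 34 of 95 (34 and 28 adjusted over the list alone; camera adjusted p = 0.607), with a median of −0.08 and a mean of 0.14. An auxin-induced 5NG4-like protein (Medtr2g007990) rose from 6.26 ± 0.463 to 53.6 ± 3.81 (2.91). Ethylene loci fell at 28, rose at 25 and were not called at 21 of 74 (28 and 25 adjusted over the list alone; camera adjusted p = 0.895), a balance that turned to 29 rises and 26 falls after median centring. The ethylene response factor Medtr1g087920 fell from 215.5 ± 5.52 to 45.45 ± 4.04 (−2.22).

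Wall, coat and tissue marker lists were not called in hsfa9-1. Cell wall loosening loci rose at 19, fell at 17 and were not called at 5 of 41 (19 and 18 adjusted over the list alone; camera adjusted p = 0.416). Medtr7g023670, a polygalacturonase-inhibiting protein that the word pattern caught, rose from 4.96 ± 0.547 to 64.9 ± 2.79 FPKM (3.47). Expansin A1 (Medtr3g064510) rose from 0.267 ± 0.174 to 25.4 ± 1.57 (4.39). Photosynthesis loci fell at 33, rose at 22 and were not called at 35 of 90 (33 and 22 adjusted over the list alone; camera adjusted p = 0.563). Oxygen-evolving enhancer protein 2-1 (Medtr5g090410) fell from 188.5 ± 12.7 to 19.2 ± 2.9 (−3.24). The light-harvesting locus Medtr5g098785 had 12.05 ± 0.6 in R108 and was listed at 0 in all hsfa9-1 libraries. Flavonoid synthesis fell at 17, rose at 13 and was not called at 10 of 40 loci (17 and 14 adjusted over the list alone; camera adjusted p = 0.895). A leucoanthocyanidin dioxygenase-like protein (Medtr5g011250) rose from 20.55 ± 0.846 to 298 ± 1.37 (3.80). Lignin synthesis rose at 14, fell at 11 and was not called at 5 of 30 loci (14 and 11 adjusted over the list alone; camera adjusted p = 0.461). Cinnamyl alcohol dehydrogenase-like Medtr5g031310 rose from 7.80 ± 0.973 to 68.5 ± 7.21 (2.98). Nodule-specific genes rose at 10, fell at 5 and were not called at 3 of 18 loci (10 and 5 adjusted over the list alone; camera adjusted p = 0.225), with 3 falls after median centring.

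Defence and housekeeping lists completed the comparison. Pathogenesis-related proteins fell at 13, rose at 12 and were not called at 14 of 39 loci (13 and 13 adjusted over the list alone; camera adjusted p = 0.895), turning to 13 rises and 12 falls after median centring. A thaumatin family locus (Medtr8g107140) rose from 0.177 ± 0.0462 to 9.29 ± 0.703 FPKM (3.13). NB-LRR disease resistance genes rose at 57, fell at 35 and were not called at 63 of 155 loci (57 and 35 adjusted over the list alone; camera adjusted p = 0.196). Antioxidant and detoxification loci fell at 41, rose at 32 and were not called at 23 of 96 (41 and 32 adjusted over the list alone; camera adjusted p = 0.563). Glutathione S-transferase Medtr2g070130 fell from 457 ± 51.5 to 52.4 ± 1.89 (−3.09). Cytosolic ribosomal proteins fell at 89, rose at 17 and were not called at 99 of 205 loci (87 and 17 adjusted over the list alone), with 67 falls and 26 rises after median centring. Their median was −0.21 (camera adjusted p = 0.0183, and adjusted p = 0.742 with an estimated correlation). Ribosomal protein S1 (Medtr6g012880) fell from 57.3 ± 2.73 to 26.6 ± 2.77 (−1.08). Proteasome and ubiquitin ligase loci fell at 49, rose at 9 and were not called at 40 of 98 (49 and 9 adjusted over the list alone). Their median was −0.19 (camera adjusted p = 0.0208, and adjusted p = 0.742 with an estimated correlation). A 26S proteasome regulatory subunit (Medtr5g027960) fell from 497 ± 8.47 to 313 ± 3.93 (−0.67). Cell cycle and histone loci rose at 32, fell at 14 and were not called at 38 of 84 (31 and 12 adjusted over the list alone; camera adjusted p = 0.225). The replication licensing factor MCM4 (Medtr4g096700) rose from 1.07 ± 0.209 to 7.93 ± 1.12 (2.11). A calcyclin-binding protein caught by the word pattern (Medtr4g084250) fell from 215 ± 18.2 to 32.4 ± 2.45 (−2.69). DNA repair loci rose at 22, fell at 17 and were not called at 22 of 61 (22 and 17 adjusted over the list alone; camera adjusted p = 0.461). A DNA ligase (Medtr2g038030) fell from 23.3 ± 0.566 to 6.21 ± 0.758 (−1.76). Of 4 retroelement loci, 2 rose and 2 were not called (2 adjusted over the list alone; camera adjusted p = 0.498). The Copia-like Medtr3g022740 rose from 1.14 ± 0.246 to 5.72 ± 0.312 (1.66).

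In all, 10412 of 17508 tested loci changed in hsfa9-1 (59.5%), 4828 higher and 5584 lower, with a median absolute log2 change of 0.66, and 2823 of them changed by at least 1. The groups did not overlap at 67.1% of tested loci, where chance gives 10%. Median centring turned the balance: genes changed hsfa9-1 vs R108 were then 5531 higher and 4888 lower. The call of list proteasome and ubiquitin ligases (F-box left out) hsfa9-1 vs R108 ended without hsfa9-1 replicate 2 (adjusted p = 0.0575, with 0.0113 to 0.0575 over the libraries left out in turn).

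The comparison of hsfa9-2 with R108 asks the same question of an independent insertion. In hsfa9-2 the BAG domain locus Medtr8g028265 fell from 425 ± 14.2 to 9.16 ± 10.7 FPKM (log2 change −5.91, adjusted p = 8.08e-06) and HSP70 locus Medtr5g006180 from 241.5 ± 22.1 to 3.81 ± 4.66 (−6.08, adjusted p = 1.89e-06). Class II small heat shock protein Medtr8g022720 fell from 142 ± 21.5 to 2.98 ± 5.06 (−5.995). Most of the remainder came from hsfa9-2 replicate 1, in which these loci had 21.51, 9.19 and 8.82 FPKM against at most 3.28, 1.13 and 0.13 in replicates 2 and 3. Flavonol synthase Medtr4g093840 rose to 1403 ± 132 (5.87, adjusted p = 6.77e-10) and xyloglucan endotransglucosylase/hydrolase Medtr4g128410 to 60.5 ± 10.03 (5.57). Among 19 loci with at least 20 FPKM in R108 and at most 1/50 of that in hsfa9-1, the median share of the R108 mean was 5.06% in hsfa9-2 replicate 1, against 0.596% and 0.673% in replicates 2 and 3 and 0.578% to 1.02% in the hsfa9-1 libraries. Replicate 1 lay above both other hsfa9-2 libraries at 19 of the 19.

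Further falls in hsfa9-2 included Medtr3g092460, class II (to 0.98 ± 1.7 FPKM, −5.88), the sugar transporter Medtr1g029380 (to 8.88 ± 10.1, −5.43) and the light-harvesting protein Medtr5g098780 (to 13.6 ± 11.3, −5.61). Other falls were those of the nucleoside transporter Medtr2g011600 (to 1.40 ± 2.2, −5.12) and a uridine kinase (Medtr4g103620; 47.2 ± 1.64 to 0.673 ± 0.959, −4.99). The SDs of these loci again came from replicate 1, with 2.94, 20.49, 26.69, 3.94 and 1.78 FPKM there. Rises included the GT8 glycosyltransferase Medtr5g036580 (to 166 ± 24.6, 5.45), a male sterility MS5 family protein (Medtr7g059010; 0.127 ± 0.0651 to 46.8 ± 10.95, 5.38) and the O-feruloyl transferase Medtr8g096530 (to 139 ± 6.05, 5.34). They also included an LRR receptor-like kinase (Medtr2g074980; 0.0133 ± 0.0115 to 36.55 ± 3.43, 5.21), a transmembrane protein (Medtr2g103750; 47.5 ± 3.25 to 1671 ± 342, 5.09) and carotenoid cleavage dioxygenase 4a-6 (Medtr5g025270, to 56.2 ± 5.63, 5.08).

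**Figure D3:**
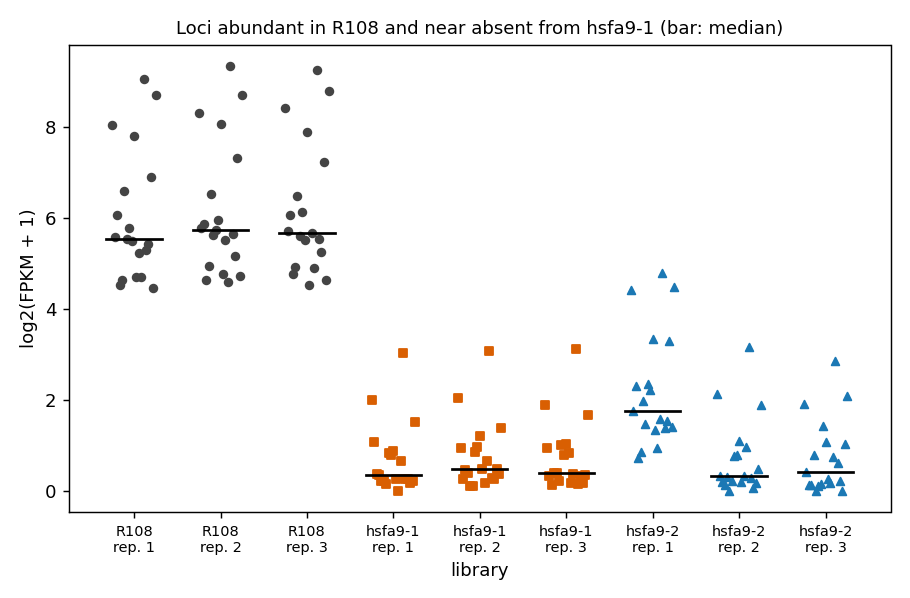
Abundance as log2(FPKM + 1) on the vertical axis in each of the 9 libraries for the 19 loci abundant in R108 and nearly absent from hsfa9-1, with 1 point per locus and a bar at the median. hsfa9-2 replicate 1 lies above the other mutant libraries, with a median of 5.06% of the R108 mean against 0.578% to 1.02%.

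Small heat shock proteins fell at 23, rose at 7 and were not called at 6 of 36 loci in hsfa9-2 (24 and 7 adjusted over the list alone). Their median was −1.05 (camera adjusted p = 0.0391, and adjusted p = 0.742 with an estimated correlation). Class II loci summed to 146 ± 21.5 FPKM and class I loci to 13210 ± 2353, or 404 ± 34.5 without Medtr5g081530, which rose to 12806 ± 2319 (1.60; chosen after its values were seen). The class I locus Medtr5g064060 fell from 43.6 ± 6.6 to 0.437 ± 0.424 (−4.98), with 0.92 in replicate 1. Heat stress transcription factors fell at 8, rose at 6 and were not called at 4 of 18 loci (8 and 6 adjusted over the list alone; camera adjusted p = 0.840), with 8 falls and 8 rises after median centring. Their median was 0.07 and their mean −0.43. Medtr4g088900 fell to 0.06 ± 0.052 (−2.67). HSP60, HSP70, HSP90 and ClpB chaperones fell at 36, rose at 16 and were not called at 12 of 64 loci (37 and 16 adjusted over the list alone; camera adjusted p = 0.170). ClpB (Medtr4g109450) rose to 1138 ± 80.5 (1.83) and the chaperonin-like RbcX protein Medtr3g061630 from 3.21 ± 0.967 to 67.9 ± 13.3 (4.04). DnaJ co-chaperones fell at 36, rose at 23 and were not called at 34 of 93 loci (36 and 23 adjusted over the list alone; camera adjusted p = 0.793), but rose at 33 and fell at 31 after median centring.

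LEA proteins and dehydrins rose at 31, fell at 22 and were not called at 10 of 63 loci in hsfa9-2 (32 and 22 adjusted over the list alone; camera adjusted p = 0.196). The embryonic abundant-like locus Medtr2g081590 rose from 523 ± 55.1 to 2536 ± 121 FPKM (2.28). Seed storage proteins rose at 16, fell at 9 and were not called at 6 of 31 loci (17 and 9 adjusted over the list alone; camera adjusted p = 0.0958), with a median of 0.50. Vicilin Medtr7g079770 rose to 923 ± 80.0 (1.60). Oil body proteins rose at 5, fell at 2 and were not called at 1 of 8 loci (5 and 2 adjusted over the list alone; camera adjusted p = 0.258), with 2 rises and 1 fall among the 5 left without the 100 most abundant loci. The oleosin Medtr3g109190 rose from 1147 ± 85.4 to 2633 ± 336 (1.19). Raffinose family oligosaccharide synthesis rose at 4 and fell at 1 of 5 loci (4 and 1 adjusted over the list alone; camera adjusted p = 0.196). Raffinose synthase Medtr3g075510 fell to 4.93 ± 1.86 (−3.68). ABA metabolism rose at 2, fell at 1 and was not called at 1 of 4 loci (2 and 1 adjusted over the list alone; camera adjusted p = 0.671), with 2 rises and 2 falls among 5 on the TPM scale. 9-cis-epoxycarotenoid dioxygenase Medtr2g070460 rose to 13.4 ± 0.277 (2.45). ABA perception and signalling rose at 9, fell at 9 and was not called at 4 of 22 loci (10 and 9 adjusted over the list alone; camera adjusted p = 0.607). AFP1 (Medtr3g025970) fell to 3.64 ± 0.806 (−3.67). Dormancy and maturation regulators fell at 3 and were not called at 1 of 4 loci (3 adjusted over the list alone; camera adjusted p = 0.448), with 2 falls after median centring. Both ABI3-interacting loci fell, Medtr8g010160 to 6.22 ± 0.511 (−0.99) and Medtr8g010170 to 224 ± 5.96 (−0.21, adjusted p = 0.00717), but median centring ended the call of Medtr8g010170 hsfa9-2 vs R108 (−0.09). Gibberellin loci fell at 11, rose at 5 and were not called at 10 of 26 (11 and 5 adjusted over the list alone; camera adjusted p = 0.924), with 10 falls and 8 rises after median centring. A gibberellin receptor (GID1, Medtr6g464510) fell from 14.9 ± 1.07 to 4.81 ± 0.441 (−1.45). Auxin loci rose at 33, fell at 32 and were not called at 30 of 95 (33 and 32 adjusted over the list alone; camera adjusted p = 0.688), turning to 31 rises and 32 falls on the TPM scale. Their median was −0.14 and their mean 0.07. Ethylene loci fell at 29, rose at 27 and were not called at 18 of 74 (29 and 27 adjusted over the list alone; camera adjusted p = 0.658), turning to 31 rises and 22 falls after median centring.

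Cell wall loosening rose at 20, fell at 16 and was not called at 5 of 41 loci in hsfa9-2 (20 and 16 adjusted over the list alone; camera adjusted p = 0.225). Expansin A1 (Medtr3g064510) rose to 29.2 ± 4.83 FPKM (4.57). Photosynthesis fell at 45, rose at 20 and was not called at 25 of 90 loci (46 and 20 adjusted over the list alone; camera adjusted p = 0.231), with a median of −0.50. Flavonoid synthesis fell at 18, rose at 12 and was not called at 10 of 40 loci (18 and 12 adjusted over the list alone; camera adjusted p = 0.988). Leucoanthocyanidin dioxygenase-like Medtr5g011250 rose to 388 ± 64.4 (4.16). Lignin synthesis rose at 14, fell at 10 and was not called at 6 of 30 loci (14 and 11 adjusted over the list alone; camera adjusted p = 0.225). Nodule-specific genes rose at 10, fell at 5 and were not called at 3 of 18 loci (10 and 5 adjusted over the list alone; camera adjusted p = 0.0704), with 3 falls after median centring. Early nodulin 93 (Medtr1g007360) rose from 7.42 ± 0.866 to 53.8 ± 10.5 (2.69). Pathogenesis-related proteins fell at 16, rose at 11 and were not called at 12 of 39 loci (16 and 12 adjusted over the list alone; camera adjusted p = 0.924), turning to 14 rises and 13 falls after median centring. NB-LRR disease resistance genes fell at 47, rose at 40 and were not called at 68 of 155 loci (47 and 39 adjusted over the list alone; camera adjusted p = 0.563), turning to 55 rises and 34 falls after median centring. Antioxidant and detoxification loci fell at 41, rose at 29 and were not called at 26 of 96 (42 and 30 adjusted over the list alone; camera adjusted p = 0.858), with 37 falls and 37 rises after median centring. Cytosolic ribosomal proteins fell at 110, rose at 15 and were not called at 80 of 205 loci (107 and 15 adjusted over the list alone), with 67 falls and 27 rises after median centring. Their median was −0.25 (camera adjusted p = 0.0183, and adjusted p = 0.742 with an estimated correlation). Proteasome and ubiquitin ligase loci fell at 54, rose at 7 and were not called at 37 of 98 (54 and 7 adjusted over the list alone), with 46 falls and 14 rises after median centring. Their median was −0.28 (camera adjusted p = 0.0131, and adjusted p = 0.742 with an estimated correlation). The ubiquitin-conjugating enzyme Medtr4g094872 fell from 187.5 ± 11.1 to 92.2 ± 9.77 (−1.02). Cell cycle and histone loci rose at 29, fell at 17 and were not called at 38 of 84 (29 and 17 adjusted over the list alone; camera adjusted p = 0.421). DNA repair loci rose at 19, fell at 18 and were not called at 24 of 61 (19 and 18 adjusted over the list alone; camera adjusted p = 0.507). Retroelements rose at 2, fell at 1 and were not called at 1 of 4 loci (2 and 1 adjusted over the list alone; camera adjusted p = 0.461).

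In all, 10902 of 17508 tested loci changed in hsfa9-2 (62.3%), 4511 higher and 6391 lower, with a median absolute log2 change of 0.67, and 3043 of them changed by at least 1. The groups did not overlap at 66.4% of tested loci, where chance gives 10%. The median log2 change of all tested loci was −0.0956 and moved to 0.0292 when values were median-centred, after which genes changed hsfa9-2 vs R108 were 5634 higher and 5070 lower. The call of list small heat shock proteins hsfa9-2 vs R108 ended without hsfa9-1 replicate 2 (adjusted p = 0.0689) or hsfa9-2 replicate 2 (0.0682; 0.0223 to 0.0689 over the libraries left out in turn), and that of list cytosolic ribosomal proteins hsfa9-2 vs R108 without hsfa9-2 replicate 1 (0.0826; 0.00295 to 0.0826).

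**Figure D4:**
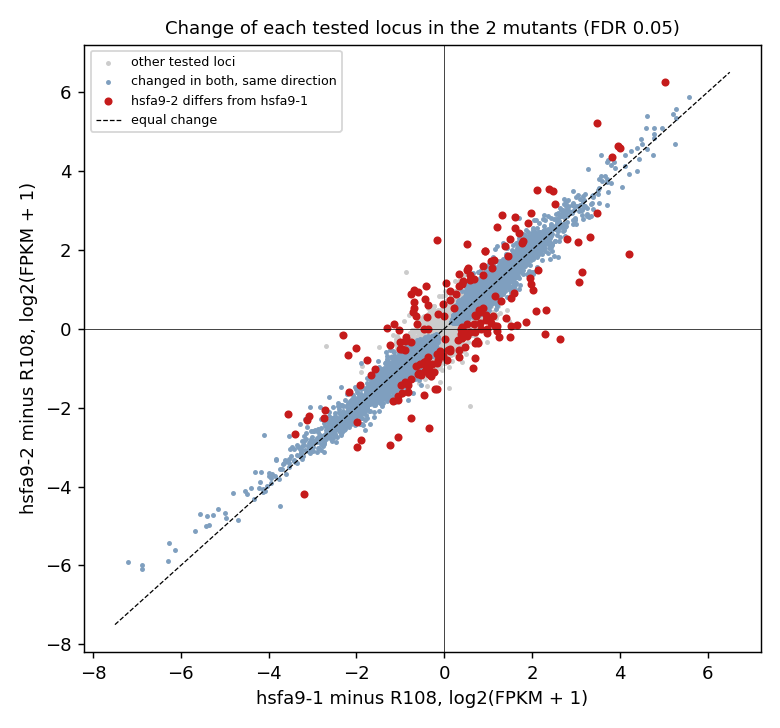
Change of each tested locus as log2(FPKM + 1) in hsfa9-1 (horizontal axis) and in hsfa9-2 (vertical axis) against R108, with 1 point per locus, loci changed in both in blue and the 196 loci that differ between the mutants in red. Most points lie along the dashed line of equal change, and Pearson's r across loci is 0.964 against 0.502 for simulated unchanged groups that share a simulated control.

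Both mutants were compared for shared changes, which asks what the lines have in common. The described loci with the largest changes in both included many of those named for each mutant, and class I small heat shock protein Medtr5g064060 (43.6 ± 6.6 FPKM in R108, 0.0867 ± 0.0751 in hsfa9-1, 0.437 ± 0.424 in hsfa9-2). A glyoxalase I family protein (Medtr4g114080), of a family that detoxifies methylglyoxal, fell from 58.4 ± 9.27 to 0.88 ± 0.13 and 1.63 ± 2.14, with 4.08 in hsfa9-2 replicate 1. A UDP-glucosyltransferase (Medtr7g067120) rose from 1.46 ± 0.431 to 65.2 ± 4.4 and 74.55 ± 12.4. Of the chaperone lists, 23 small heat shock proteins fell and 6 rose in both mutants, 8 heat stress transcription factors fell and 4 rose, and 32 HSP60, HSP70, HSP90 and ClpB chaperones fell and 16 rose. Ribosomal proteins fell in both at 82 loci and rose at 11, and proteasome and ubiquitin ligase loci fell at 46 and rose at 6. LEA proteins and dehydrins rose in both at 26 loci and fell at 21, and storage proteins rose at 9 and fell at 7. Legumin A2 (Medtr7g096990; 2748 ± 177, 2158 ± 412 and 4179 ± 568 FPKM; chosen after its values were seen) was called in opposite directions (−0.36 and 0.60).

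A total of 9340 loci changed in the same direction in both mutants (53.3% of those tested), 4095 higher and 5245 lower, 14 were called in opposite directions, 1058 were called in hsfa9-1 alone and 1548 in hsfa9-2 alone. Independent lists of these sizes would share 1244 higher and 2038 lower loci, and unchanged groups with a shared simulated control shared 0 calls. That simulation held no real R108 library, so an unusual batch of R108 could not show in it. Across loci the log2 changes had Pearson's r of 0.964 and Spearman's rho of 0.946, against r of 0.502 in the simulation, and the same sign at 89.9% of loci against 66.6%. Their covariance was 0.712 against 0.0115 simulated, a difference of 0.701. Because 3 control libraries could not be split into groups of at least 2, part of the excess over independent lists may come from the shared controls.

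**Figure D5:**
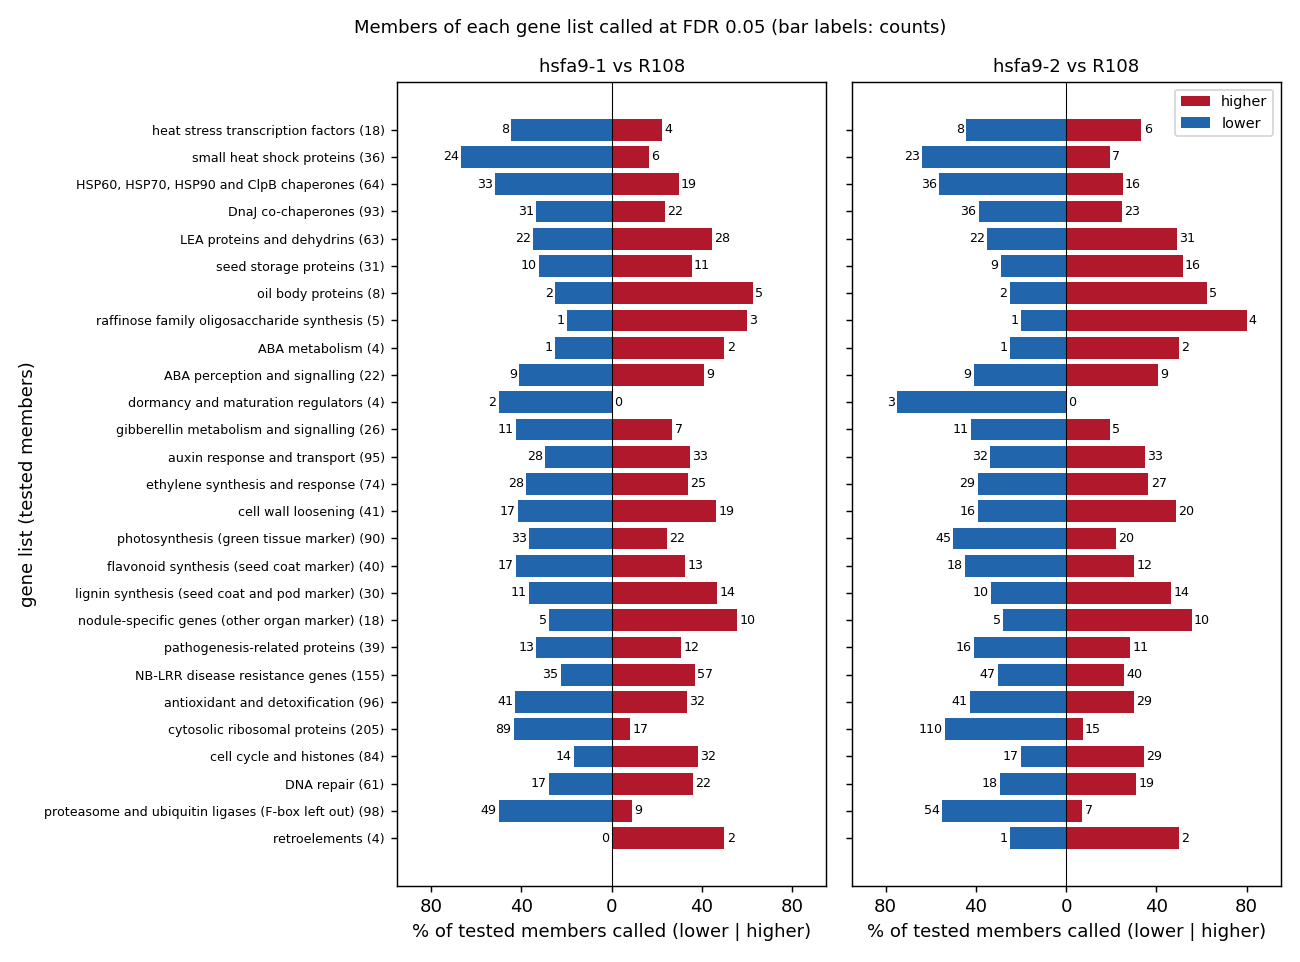
Percent of the tested members of each gene list that were higher (red, to the right) or lower (blue, to the left) in hsfa9-1 and in hsfa9-2 than in R108 at an adjusted p under 0.05, with counts at the bars. Small heat shock proteins, cytosolic ribosomal proteins and proteasome loci fell more often than they rose in both mutants, and the balances of the ethylene, pathogenesis-related, DnaJ, NB-LRR and auxin lists turned under another scaling in at least 1 mutant. Those of the heat stress transcription factor, antioxidant, oil body and ABA metabolism lists became even under another scaling in at least 1 mutant.

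The comparison of hsfa9-2 with hsfa9-1 asks whether the lines differ from each other. The LRR receptor-like kinase Medtr2g074980 was higher in hsfa9-2, with 10.5 ± 2.22 FPKM in hsfa9-1 and 36.55 ± 3.43 in hsfa9-2 (log2 change 1.72, adjusted p = 0.000322). A mechanosensitive ion channel-like protein (Medtr3g100320) had 8.95 ± 1.82 and 29.6 ± 6.64 (1.61) and prephenate dehydrogenase (Medtr5g083530), of tyrosine synthesis, 0.187 ± 0.107 and 2.82 ± 0.577 (1.68). Also higher were a DUF4057 protein (Medtr7g008860; 0.233 ± 0.202 and 2.83 ± 0.728, 1.63) and a Bowman-Birk trypsin inhibitor (Medtr7g077215; 13.0 ± 3.65 and 38.95 ± 6.86, 1.53). Lower in hsfa9-2 were a P-loop nucleoside triphosphate hydrolase (Medtr8g066210; 18.3 ± 0.913 and 2.83 ± 0.106, −2.33, adjusted p = 4.54e-06) and a transmembrane protein (Medtr7g033305; 17.9 ± 9.75 and 1.26 ± 0.161, −2.90). So were an RsbQ-like protein (Medtr3g045440; 14.9 ± 1.84 and 3.29 ± 0.172, −1.89) and a myb transcription factor (Medtr4g478180; 4.01 ± 0.131 and 0.39 ± 0.0693, −1.85). The C2H2 zinc finger locus Medtr1g077120 had 4.65 ± 2.03 in hsfa9-1 and was listed at 0 in all hsfa9-2 libraries.

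A few storage and small heat shock protein loci were higher in hsfa9-2 than in hsfa9-1. Of 31 storage loci, 5 were higher and 0 lower (13 and 1 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 2.62e-10, and adjusted p = 0.397 with an estimated correlation). All 5 were chosen after their values were seen, and included the vicilins Medtr1g103400 (310 ± 44.7 and 598 ± 77.4 FPKM, 0.95) and Medtr7g079820 (25.1 ± 2.71 and 39.1 ± 5.44, 0.62). The others were the 2S albumins Medtr2g083110 (1631 ± 330 and 3221 ± 118, 1.00) and Medtr2g083160 (451 ± 127 and 1230 ± 111, 1.48), and legumin A2 (Medtr7g096990, 0.96). Of 36 small heat shock proteins, 2 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 2.62e-10, and adjusted p = 0.742 with an estimated correlation). They were the class I loci Medtr4g088490 (40.7 ± 3.92 and 71.6 ± 2.9, 0.80) and Medtr5g081530 (0.71, chosen after its values were seen). Replicate 1 of hsfa9-2 stood apart in some near-absent members, such as Medtr8g022720 (8.82 FPKM against 0.13 and 0 in replicates 2 and 3). Summed class II FPKM was 157, 121 and 159 in hsfa9-2 replicates 1, 2 and 3. LEA proteins and dehydrins had a median of 0.09 and 1 locus higher (1 adjusted over the list alone), Medtr2g081590 (1463 ± 93.6 and 2536 ± 121, 0.79), with camera adjusted p = 2.43e-05 and adjusted p = 0.742 with an estimated correlation.

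Nodule-specific genes had a median of 0.20 and 1 locus higher (2 adjusted over the list alone), early nodulin 93 (Medtr1g007360; 30.2 ± 2.4 and 53.8 ± 10.5 FPKM, 0.80), with camera adjusted p = 0.00145 and adjusted p = 0.742 with an estimated correlation. Photosynthesis had a median of −0.18 and 0 loci called (1 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.0338, and adjusted p = 0.742 with an estimated correlation). NB-LRR genes had a median of −0.12, with Medtr4g023260 higher (0.66) and Medtr5g027870 lower (−1.05), both chosen after their values were seen. Adjusted over the list alone there were 1 and 2 (camera adjusted p = 0.0106, and adjusted p = 0.742 with an estimated correlation). Antioxidant loci had a median of 0.0142 and 0 calls, also adjusted over the list alone (camera adjusted p = 0.0299, and adjusted p = 0.742 with an estimated correlation). In lists that camera did not call, ClpB (Medtr4g109450) was higher by 0.39 and heat shock cognate 70 kDa protein (Medtr7g024580) lower (−0.32), gibberellin-regulated Medtr1g018640 was higher by 0.88 (50.1 ± 10.01 and 92.55 ± 14.3), and polygalacturonase-inhibiting Medtr7g023670 was lower (−0.53). Members chosen after their values were seen were spermidine hydroxycinnamoyl transferases of the lignin list (Medtr7g085930, 0.80; Medtr7g085990, 0.76), and DnaJ locus Medtr4g080350 (0.53). The others were xyloglucan endotransglucosylase Medtr4g128400 (0.59), histone H4 Medtr7g029520 (1.049), a 26S proteasome ATPase (Medtr3g117230, −0.39) and a ubiquitin-conjugating enzyme (Medtr8g098615, −0.64). The remaining lists, among them heat stress transcription factors, oil body, auxin, ethylene, flavonoid, ribosomal and DNA repair loci, had 0 members called. Adjusted over the list alone, 1 member was higher in each of the heat stress factor, oil body, flavonoid, raffinose and pathogenesis-related lists. Likewise 1 auxin locus was higher and 1 lower, and 1 locus of ABA perception and signalling was lower.

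In all, 196 loci differed between the mutants (1.12% of those tested), 86 higher and 110 lower in hsfa9-2, 61 of them by at least 1 on the log2 scale, and 2592 had an unadjusted p under 0.05. The groups did not overlap at 19.1% of tested loci, where chance gives 10%, and after median centring the genes differing hsfa9-2 vs hsfa9-1 were 114 higher and 78 lower. Single libraries moved this count by more than 1.5 times: it was 115 without R108 replicate 3, 125 and 94 without hsfa9-1 replicates 1 and 2, between these without hsfa9-1 replicate 3, and 324, 102 and 120 without hsfa9-2 replicates 1, 2 and 3. Several list calls also ended without single libraries. The list photosynthesis (green tissue marker) hsfa9-2 vs hsfa9-1 had adjusted p = 0.259, 0.112, 0.0505 and 0.213 without hsfa9-1 replicates 2 and 3 and hsfa9-2 replicates 1 and 2. The list NB-LRR disease resistance genes hsfa9-2 vs hsfa9-1 had 0.182 and 0.0826 without hsfa9-1 replicate 2 and hsfa9-2 replicate 1, and the list antioxidant and detoxification hsfa9-2 vs hsfa9-1 had 0.120 and 0.163 without hsfa9-1 replicate 2 and hsfa9-2 replicate 2.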

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

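The tests of composition, of depth, of linked regions, of an R108 seed lot or batch, of copies of small heat shock proteins and of the growth history of R108 were chosen only after the result was seen.

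A test of hsfa9-2 against hsfa9-1 in limma found that 196 loci changed by different amounts from R108 in the mutants. Among loci with an informative description, a mean of at least 1 FPKM and no overlap of the mutants, the largest log2 differences of hsfa9-2 minus hsfa9-1 were 1.72 for LRR receptor-like kinase Medtr2g074980, 1.68 for prephenate dehydrogenase Medtr5g083530, 1.63 for DUF4057 locus Medtr7g008860, 1.61 for mechanosensitive channel Medtr3g100320 and 1.53 for trypsin inhibitor Medtr7g077215. In the other direction they were −2.90 for transmembrane protein Medtr7g033305, −2.43 for zinc finger locus Medtr1g077120 (listed at 0 in hsfa9-2, so that the value depends on the pseudocount), −2.33 for P-loop hydrolase Medtr8g066210, −1.89 for RsbQ-like Medtr3g045440 and −1.85 for myb factor Medtr4g478180. Members of gene lists differed by 0.80 (class I small heat shock protein Medtr4g088490), 0.39 (ClpB, Medtr4g109450), −0.32 (heat shock cognate Medtr7g024580), 0.79 (embryonic abundant-like Medtr2g081590), 0.88 (gibberellin-regulated Medtr1g018640), −0.53 (polygalacturonase-inhibiting Medtr7g023670) and 0.80 (early nodulin 93, Medtr1g007360). The lists called between the mutants with the preset correlation, none of which stayed called with an estimated correlation (adjusted p = 0.742, and 0.397 for seed storage proteins), had median differences of 0.30 (small heat shock proteins), 0.0898 (LEA proteins and dehydrins), 0.24 (seed storage proteins), −0.18 (photosynthesis), 0.20 (nodule-specific genes), −0.12 (NB-LRR genes) and 0.0142 (antioxidant loci).

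Most of the tested loci differed from R108 in both mutants. Library composition is argued against as the whole cause, because 8394 of the 9340 loci remained called after the 100 most abundant loci were left out and the rest rescaled and centred, and so is depth, since the largest relative depth was 1.02 times the smallest. Of 100 drawn splits of the 9 libraries into groups of 3, 1 gave as many loci called in both (the real one, 9340). The others gave at most 1 locus, but 0 of them kept the R108 libraries together. Mixing R108 with mutant libraries widens the spread within groups, so the low counts of these splits leave chance undecided. The 10 splits of each mutant with R108 are too few for a share under 0.05 (10412 loci in hsfa9-1 with at most 0 in the others, and 10902 in hsfa9-2 with at most 2). A seed lot, harvest or library batch of R108 cannot be told apart from the mutations, because 0 mutant libraries lay among those of R108 on the first principal component and the labels give no harvest or batch. A shared effect of losing HSFA9 stays open beside it, as does a difference in background between R108 and both lines.

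Of 36 small heat shock proteins, 23 fell and 6 rose in both mutants, and the call of the list ended with an estimated correlation (adjusted p = 0.742 in each). For the 4 loci described as class II small heat shock proteins, summed FPKM reached at most 0.131 of the R108 mean in any mutant library. This argues against reads assigned from 1 of these 4 copies to another. Class II copies described in other words were not summed, so a shift of reads to such copies was not tested. For class I, reads assigned to another copy cannot be told apart from a loss. The sum of its 11 members was at least 1.27 times the R108 mean in every mutant library, through Medtr5g081530. A warmer or more stressed growth history of the R108 plants also stays open, with 32 of the HSP60, HSP70, HSP90 and ClpB chaperones lower and 16 higher in both mutants, and ClpB itself higher. Loss of activation by HSFA9 is a candidate explanation for class II that these data leave open, since no binding data were used here.

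Between hsfa9-2 and hsfa9-1, 55.1% of the 196 loci remained called without hsfa9-2 replicate 3, the library farthest out on the second principal component, and 156 remained after the 100 most abundant loci were left out, which argues against that library or composition as the whole cause. Fewer of the 196 remained without hsfa9-1 replicate 1, 2 or 3 (102, 85 and 103) or without hsfa9-2 replicate 2 (95). Linked genomic regions cannot be told apart from other causes, with 42 neighbouring pairs of called loci against a mean of 37.9 in random sets (permutation p = 0.2355, 191 loci on chromosomes). The 10 splits of the mutant libraries are too few for a share under 0.05, with 196 loci in the real split and at most 0 in the others. Different insertions elsewhere in the genome, different strength of the alleles and different seed lots stay open as untested.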

How the results depend on the processing

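The transcript model, TPM scale, abundant-locus, quantile and leguminosin alternatives were tests chosen only after the result was seen. The genes changed hsfa9-1 vs R108, genes changed hsfa9-2 vs R108 and genes changed in both mutants stayed within 1.5 times their counts under every alternative run except the larger change required below, with 9418 to 10691, 9915 to 10765 and 8413 to 9188 when libraries were left out in turn, and of the loci called in both, 8142 to 9219 were shared with each alternative that kept the threshold and the sum per locus. For 93 named loci in 3 comparisons, 4902 of 4998 alternative results kept their direction and side of the threshold, 83 lost the call, 13 gained one and 0 reversed. Of the lost calls, 17 were in hsfa9-1 vs R108 and 5 in hsfa9-2 vs R108, and the rest were between the mutants. Absolute depth is unknown, which limits what can be said of loci near 0 FPKM. DESeq2 size factors, the DESeq2 Wald test and library totals were not run, since no counts were used here. Replicate numbers did not pair the libraries (residual correlations of −0.125 to 0.0960 in 9 pairs, 0 over 0.1, and 2 of 9 libraries correlating best with their own number). With the replicate block, counts were 10213, 10716, 9160 and 145 for hsfa9-1, hsfa9-2, both and hsfa9-2 against hsfa9-1, and of list calls only 1 ended (list photosynthesis (green tissue marker) hsfa9-2 vs hsfa9-1, 0.0552). The cause was not tested for any of the changes that follow. Stricter thresholds lower counts by construction, and fewer libraries lower power. Lower power does not account for the larger count of differing loci without hsfa9-2 replicate 1.

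The genes differing hsfa9-2 vs hsfa9-1 (196) were 126 with no low-expression filter, 104 with only the groups compared in the fit, 87 with transcript models as features, 80 at a threshold of 0.01, and 94 (without hsfa9-1 replicate 2) to 324 (without hsfa9-2 replicate 1) with a library left out in turn, and leaving out R108 replicate 3 or any other mutant library also moved it by more than 1.5 times. Requiring an absolute log2 change of at least 1 gave 2823, 3043, 2513 and 61 for hsfa9-1, hsfa9-2, both and the mutants against each other. The number of gene lists called hsfa9-2 vs hsfa9-1 was 4 with no low-expression filter and 4 (without hsfa9-1 replicate 2) to 8 with a library left out.

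With an estimated correlation camera called 0 lists in hsfa9-1, 0 in hsfa9-2 and 0 between the mutants. Adjusted p was 0.397 for storage proteins between the mutants and 0.742 for each other list called in the main test. The equal values come from the adjustment. Before it, camera p for those other lists ran from 0.0235 (small heat shock proteins between the mutants) to 0.381 (cytosolic ribosomal proteins in hsfa9-2). fry called 20 lists in hsfa9-1 and 19 in hsfa9-2. In hsfa9-1 it gained heat stress transcription factors (7.933e-05), HSP60 to ClpB chaperones (0.000202), DnaJ (0.000623), oil body (0.0363), raffinose (0.000373), ABA metabolism (0.00868), dormancy (7.07e-05), auxin (0.000517), wall loosening (3.36e-05), photosynthesis (0.0452), lignin (0.00267), nodule (0.0019), NB-LRR (0.0198), antioxidant (0.0176), cell cycle (0.0284) and retroelements (0.0025). In hsfa9-2 it gained heat stress transcription factors (8.97e-05), HSP60 to ClpB chaperones (7.93e-05), DnaJ (0.000202), LEA (0.0198), storage (0.00198), oil body (0.00819), raffinose (8.43e-05), ABA metabolism (0.00267), dormancy (3.36e-05), wall loosening (3.36e-05), photosynthesis (0.00361), lignin (0.00178), nodule (0.000391), antioxidant (0.027) and retroelements (0.00434). Flavonoid synthesis, which camera did not call, was called higher by fry (0.0142 in hsfa9-1, 0.00767 in hsfa9-2); fry tests against no change and camera against other loci. Between the mutants fry gained HSP60 to ClpB chaperones (0.0459), raffinose (0.0363), dormancy (0.0341) and auxin (0.00267), and lost LEA (0.173), photosynthesis (0.0884), nodule (0.0734) and antioxidant (0.755).

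With no low-expression filter, list small heat shock proteins hsfa9-2 vs R108 had 0.0654, and between the mutants list photosynthesis (green tissue marker) hsfa9-2 vs hsfa9-1 had 0.406, list NB-LRR disease resistance genes hsfa9-2 vs hsfa9-1 had 0.537 and list antioxidant and detoxification hsfa9-2 vs hsfa9-1 had 0.0654. With libraries left out in turn these ran from 0.0223 to 0.0689, 5.66e-05 to 0.259, 0.000219 to 0.182 and 0.0181 to 0.163. The calls ended without hsfa9-1 replicate 2 for all of these, without hsfa9-2 replicate 2 for all but NB-LRR genes, without hsfa9-2 replicate 1 for photosynthesis and NB-LRR genes, and without hsfa9-1 replicate 3 for photosynthesis. The list proteasome and ubiquitin ligases (F-box left out) hsfa9-1 vs R108 ran from 0.0113 to 0.0575 (without hsfa9-1 replicate 2) and list cytosolic ribosomal proteins hsfa9-2 vs R108 from 0.00295 to 0.0826 (without hsfa9-2 replicate 1). The list nodule-specific genes (other organ marker) hsfa9-2 vs R108 ran from 0.0447 (without R108 replicate 1) to 0.109, list oil body proteins hsfa9-2 vs hsfa9-1 from 0.0185 to 0.209 (called without R108 replicate 1, hsfa9-1 replicate 3 or hsfa9-2 replicate 3), and list lignin synthesis (seed coat and pod marker) hsfa9-2 vs hsfa9-1 from 0.0488 (without hsfa9-1 replicate 1) to 0.645. Without leguminosin peptides, list seed storage proteins hsfa9-1 vs R108 had 0.895, list seed storage proteins hsfa9-2 vs R108 had 0.106 and list seed storage proteins hsfa9-2 vs hsfa9-1 had 8.51e-10.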

Other observations

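The test of the differences between mutants without hsfa9-2 replicate 1 was chosen only after the result was seen.

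Ontology terms were tested by one-sided Fisher's exact tests, and some overlap the fixed lists. These tests treat loci as independent, so their p-values may be too small. No camera call of the fixed lists held with an estimated correlation. The terms were tested only on calls without median centring, which turned the balance of higher and lower loci in each mutant. Loci lower in both mutants were enriched in terms of membrane trafficking: 71 of 123 tested loci of the endoplasmic reticulum membrane fell in both (36.8 by chance, adjusted p = 1.38e-07), as did 71 of 126 of intracellular protein transport (adjusted p = 3.04e-07), 17 of 20 of Golgi to endoplasmic reticulum transport (adjusted p = 0.000151), 30 of 51 of the opposite route (adjusted p = 0.00162) and 63 of 126 of the trans-Golgi network (adjusted p = 0.000306). Separate terms enriched among the same loci were respiratory chain complex I, with 17 of 22 loci lower in both (adjusted p = 0.000736), and glycolysis, with 25 of 42 (adjusted p = 0.00412). Protein folding had 63 of 138 loci lower in both (adjusted p = 0.00412). In all, 21 of 1028 terms passed among loci lower in both and 14 among loci higher in both.

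Loci higher in both mutants were enriched in an RNA-binding PPR orthology group (65 of 172 loci, 40.2 by chance, adjusted p = 0.0102), trehalose biosynthesis (10 of 14, adjusted p = 0.0288), monooxygenases (26 of 57, adjusted p = 0.0288), amino acid transmembrane transport (21 of 44, adjusted p = 0.036), sulfotransferases (9 of 13, adjusted p = 0.046) and nucleolin-like proteins (13 of 23, adjusted p = 0.046). Among loci that differ between the mutants, 0 terms passed in either direction by Fisher's exact test, with few loci called there (196).

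Transcripts nearly absent from the other mutant libraries were present at low level in hsfa9-2 replicate 1, and R108-like RNA in that library is a candidate explanation. In 19 loci chosen on R108 and hsfa9-1 alone, the excess of replicate 1 over the other hsfa9-2 libraries had a median of 4.17% of the R108 mean (quartiles 3.27% and 5.35%), with 3.28% for 6 chaperones and 4.70% for 13 other loci. A second set of 15 loci, for which a similar excess was predicted before it was computed, had a median of 3.66% (quartiles 2.78% and 4.38%), and replicate 1 was above both others at 14 of them. R108 or heterozygous seeds among the 50, carry-over of RNA between samples and residual activity in some seeds could each give such an excess, and no test here separates them. Of the 196 loci that differ between the mutants, 165 remained called without this library, which argues against such RNA as the cause of most of them. The count of differing loci was larger without this library, as given above, so it does bear on this comparison.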
